A study of Homo sapiens with 2 samples.

How the data were processed

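Total RNA of U251 glioblastoma cells was extracted with Trizol, and biotin-labelled cRNA was made from 6 µg of it for Affymetrix arrays, per the labels' protocols. The cells had been grown in high-glucose DMEM and given DMSO or 5 µM G-TPP for 6 h. Each condition has 1 array, and groups were taken from the agent named in the labels.

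The deposited table holds 1 intensity per probe set and array on a linear scale, as its values from 6.61 to 18995 show. Per the submitters' processing notes the authors used RMA in Affymetrix Expression Console 1.1.2. RMA corrects background, makes the intensity distributions of arrays alike and summarises probes, so a change in the total amount of RNA per cell is not visible in these values. Which arrays entered the RMA run, whether probes were filtered and how the values came to a linear scale are not given in the sources used here. Scanner files were not used here. For arrays, their number limits the precision, and here that is 1 per group.

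Probe sets were named through the platform's annotation, with gene IDs looked up in the RefSeq gene table of assembly GRCh38.p14 for the current symbol. Of 33297 probe sets, 19460 had 1 gene symbol, 1754 had several and 12083 were not listed in the annotation. Gene IDs of 19429 of the first kind were in the RefSeq table and 31 were not, and the annotation's own symbol was kept for these. No gene was named from a probe set with several symbols. The named probe sets gave 18417 genes, 769 of them with more than 1 probe set, for which the probe set with the highest mean intensity was used.

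The log2 of each deposited intensity was taken with no pseudocount, and the difference G-TPP minus DMSO was computed per gene. A gene was kept if the intensity in its brighter array reached a filter, which left 11091 genes. The filter was the median over all probe sets of the value in their brighter array, a log2 intensity of 7.90 (intensity 239.2). With 1 array per group no test can be made, so genes were counted by size, at an absolute log2 difference of 1 or more, which is 2-fold. Folds are ratios of the deposited intensities of both arrays, and background left in dim probe sets pulls them towards 1. For a named gene whose dimmer array was under the 95th percentile of the olfactory receptors in that array (172.6 with DMSO, 173.6 with G-TPP), the fold was taken against that floor and given as a lower bound, a rule chosen after the data were seen.

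Before the data were examined 38 gene lists were fixed: stress responses, mitochondrial functions, signalling, cell cycle, metabolism, structural gene families, markers of the culture and of foreign cell types, and olfactory receptors as genes near the floor. Each list's median log2 difference over its kept genes was placed among 10000 random lists of the same size, drawn from the kept genes in 20 bins of mean brightness. A list was said to lie outside if its median was among the lowest 0.5% or the highest 0.5% of theirs, and 33 lists with at least 5 kept genes were placed. Genes of a list vary together, so a list can lie outside by chance more often than the percentile says.

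Outside the part on other observations, the genes named in the report follow a rule fixed before the data were examined. It takes the 15 highest and the 15 lowest log2 differences among kept genes. Up to 4 kept members with the largest absolute difference per list were added. A fixed set of chaperone, stress and control genes was also named, which includes TRAP1, HSPD1, HSPE1, HSPA9, CLPP, LONP1, DDIT3, CEBPB and ATF4.

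The procedure was tested on simulated data for the comparison of G-TPP with DMSO, with 11091 genes. The size rule took 44% of genes changed by 2-fold, 100% of genes changed by 4-fold and 0.13% of unchanged genes. Of unchanged lists of 25 genes 1.7% came to lie outside, and of lists shifted by 0.5 on the log2 scale 100% were called higher. The simulated noise was normal and independent between genes. Its spread in each brightness bin came from the median absolute deviation of the differences between these same 2 arrays. Heavier tails were left out and no replicate culture entered, so the 0.13% is no rate of false calls in these data.

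Alternatives fixed in advance were thresholds of 1.5-fold and 3-fold, no brightness filter, a filter at the 75th percentile or on the mean of both arrays, lowess centring on brightness with a span of 0.3, centring on the median, quantile normalization, other choices among probe sets, log2 of the intensity plus 16, the list mean, 5 bins, and lists without shared genes. Leaving out a replicate was not possible. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Probe sets without a single symbol were left out of every gene comparison because they name no single gene.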

Results

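Gene expression was measured in U251 cells, an established human glioblastoma line, after 6 h with either the solvent DMSO or 5 µM G-TPP. G-TPP is the Gamitrinib in which a geldanamycin-type Hsp90 inhibitor is joined to triphenylphosphonium, a lipophilic cation that accumulates in mitochondria. Hsp90-type chaperones of mitochondria, TRAP1 among them, are its intended target, and the comparison asks how transcripts, above all those for mitochondrial proteins, differ between G-TPP and DMSO. Inhibition of the chaperones was not measured here. There was 1 array for DMSO and 1 array for G-TPP. The deposited intensities of the 33297 probe sets had a median of 224.8 in the DMSO array and 215.5 in the G-TPP array, with maxima of 18995 and 17912. With 1 array per group the difference between the arrays has no replicate check, so no value below carries a standard error or a p-value, and "higher" and "lower" describe these 2 arrays.

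Stress-response genes of the cytosol and endoplasmic reticulum (ER) were far higher in the G-TPP array, while genes for mitochondrial chaperones were not. Of 11091 genes kept after the brightness filter, 310 were at least 2-fold higher with G-TPP and 61 at least 2-fold lower, and at 4-fold the counts were 57 and 0. HSPA6 (probe set 7906764), a strictly stress-inducible cytosolic Hsp70, was the gene with the highest fold, at an intensity of 307.1 with DMSO and 6761 with G-TPP, 22.01-fold higher. CTH (probe set 7902290), the cystathionine gamma-lyase of cysteine synthesis, was 19.99-fold higher, and the ER cochaperone gene DNAJB9 and the haem oxygenase gene HMOX1 were 13.0-fold and 10.5-fold higher. At the low end SNORD30, a small nucleolar RNA, was 3.78-fold lower, and PDGFRA, the platelet-derived growth factor receptor alpha, went from 1592 to 490.1, 3.25-fold lower.

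**Figure D1:**
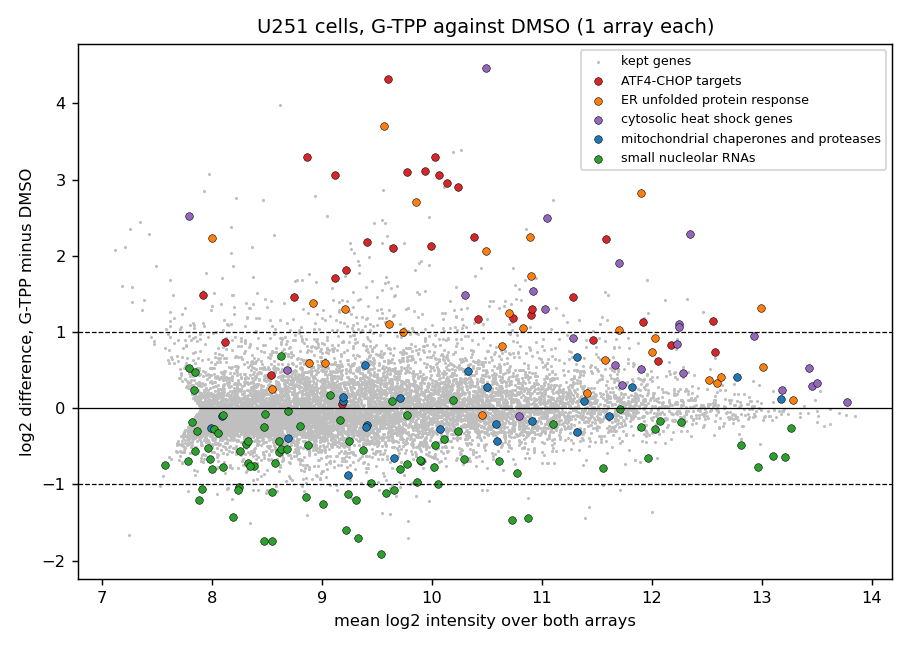
Log2 difference between the G-TPP and the DMSO array (vertical axis) against mean log2 intensity of both arrays (horizontal axis) for the 11091 kept genes, 1 point per gene, with 5 gene lists in colour and dashed lines at 2-fold. Most coloured points of the ATF4-CHOP, ER and cytosolic heat shock lists lie above 0, those of the mitochondrial chaperones and proteases lie between the dashed lines, and small nucleolar RNAs lie mostly below 0.

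The kept genes had a median log2 difference of -0.04 with a standard deviation across genes of 0.43, and the log2 intensities of the 2 arrays correlated across genes with r = 0.94; genes are not independent replicates. The spread of signals that carry little or no expression gives a scale for array noise. Among 341 olfactory receptor genes, which are mostly silent outside the nose, the log2 differences had a standard deviation of 0.19 and none reached 2-fold. In 328 genes with a pair of probe sets above the filter, the differences of the pair scattered with a standard deviation of 0.17 per probe set. Both guides leave out differences between cultures, which were not measured. The olfactory receptors had a median intensity of 68.5 with DMSO, under the filter, so their spread need not hold for kept genes. Probe sets of 1 gene can give the same difference, as the 3 of MRPS18B did, and such pairs would narrow the scatter.

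The integrated stress response stood out. All 32 kept members of the list of ATF4 and CHOP target genes were above 0 in log2 difference, 25 were at least 2-fold higher, and their median log2 difference of 1.60 lay above all 10000 random lists of genes with like brightness. DDIT3, which encodes the transcription factor CHOP, went from 371.6 to 3104 (8.35-fold higher). PPP1R15A, which encodes the phosphatase subunit GADD34, was 9.83-fold higher, and the mitochondrial folate enzyme gene ALDH1L2 at least 8.45-fold higher. CHAC1, a glutathione-degrading enzyme, SESN2 and the pseudokinase gene TRIB3 were 8.63-fold, 8.58-fold and 7.78-fold higher. The secreted stress cytokine GDF15 and the mTORC1 inhibitor DDIT4 were 8.37-fold and 7.47-fold higher. Among the factors themselves CEBPB was 2.26-fold higher and ATF3 at least 2.35-fold higher. ATF4 was 2.33-fold higher by its brighter probe set, but its other probe set had a log2 difference of -0.43, and the mean over both was 0.40, below 2-fold. Cytosolic tRNA synthetases had a median log2 difference of 0.61 over 19 genes, above all 10000 random lists, and 5 were at least 2-fold higher, among them GARS1 (2.68-fold), CARS1 (2.66-fold), WARS1 (2.49-fold) and AARS1 (2.38-fold). The other 14 did not reach 2-fold, and 7 of the 19 were below 0.

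**Figure D2:**
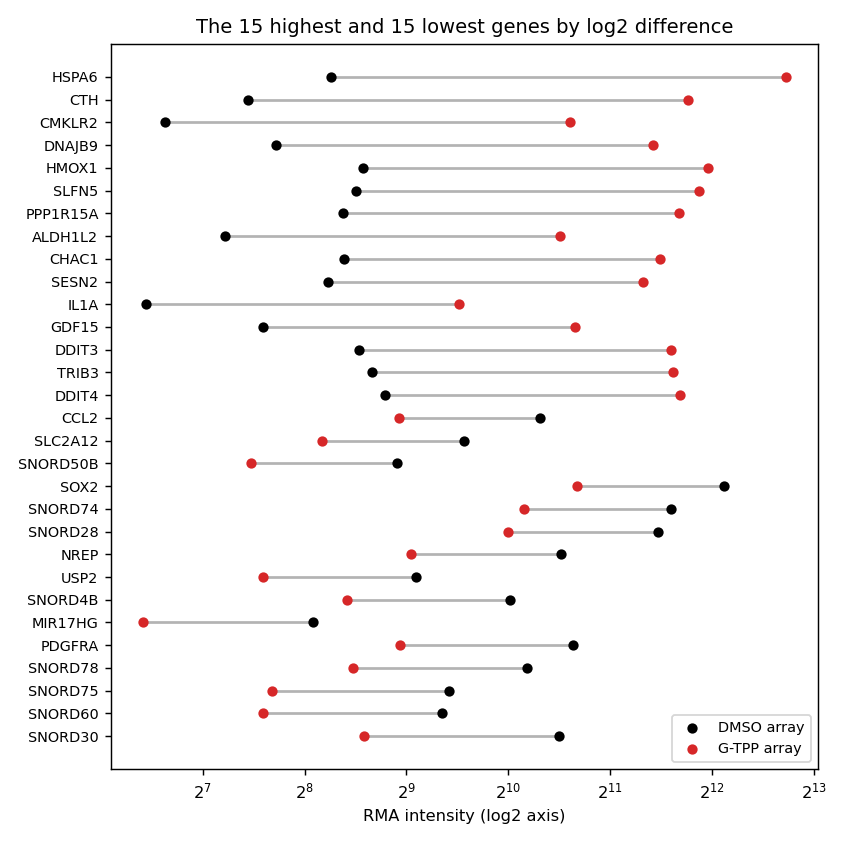
RMA intensity on a log2 axis for the 15 genes with the highest and the 15 with the lowest log2 difference, black for the DMSO array and red for the G-TPP array, 1 value each. HSPA6 spans the widest distance, from 307.1 to 6761, and among the 15 lowest the widest is SNORD30, from 1447.7 to 382.5.

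The unfolded protein response of the ER was also higher. The median of 29 kept members was 2.01-fold higher, above all 10000 random lists, 15 were at least 2-fold higher and none at least 2-fold lower. HERPUD1, an ER-associated degradation factor, went from 1437 to 10138 (7.06-fold higher), and the COPII coat gene SEC24D was 6.53-fold higher. XBP1, the transcription factor of the IRE1 branch, was 4.73-fold higher, and HSPA5, the Hsp70 of the ER known as BiP, was 2.48-fold higher. HSP90B1, the Hsp90 of the ER, was 1.45-fold higher and did not reach 2-fold.

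Cytosolic heat shock genes had a median log2 difference of 0.88 over 24 kept members, above all 10000 random lists, and 23 of the 24 were above 0. At least 2-fold higher were 10, among them HSPA6, the Hsp40 genes DNAJB4 (5.64-fold) and DNAJB1 (4.89-fold) and the small heat shock protein gene CRYAB (at least 3.09-fold). The cytosolic Hsp90 genes differed little, with HSP90AA1 1.18-fold and HSP90AB1 1.22-fold higher. HSPA1A and HSPA1B have no probe set of their own in the annotation and are not reported. HSPA6 belongs to the same family, and near-identical copies can share probes, as can metallothionein, histone, AKR1C and small nucleolar RNA genes.

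Chaperones and proteases of mitochondria did not differ as a group. The median log2 difference over 24 kept members was -0.10, within the range of the random lists at the percentile 7.58, with 11 members above 0, 13 below and none at 2-fold in either direction. After lowess centring the median was -0.04. HSPD1 (Hsp60) was 1.09-fold, HSPE1 (Hsp10) 1.40-fold, HSPA9 (mortalin) 1.33-fold and the matrix protease gene LONP1 1.47-fold higher, while the protease gene CLPP was 1.12-fold lower. GRPEL2, a nucleotide exchange factor, was 1.59-fold higher, whereas the mitochondrial processing peptidase subunit PMPCA was 1.83-fold and the protease gene HTRA2 1.57-fold lower. TRAP1 itself had a log2 difference of -0.31 by its brighter probe set, at 2850 with DMSO and 2297 with G-TPP, and 0.06 by its other probe set.

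Nuclear genes of the respiratory chain lay slightly low. Subunits of complexes II to V had a median log2 difference of -0.13 over 35 genes, and 41 of the 10000 random lists were as low; 30 of the 35 were below 0 and none reached 2-fold. UQCRB of complex III (1.63-fold lower), SDHA of complex II (1.54-fold lower) and the ATP synthase genes ATP5F1A (1.40-fold lower) and ATP5MC1 (1.39-fold lower) differed most. This call was lost with no brightness filter, at the 75th percentile filter and without genes shared between lists, where the median was -0.12 each time. Complex I had a median of -0.10 over 34 genes and lay within the random lists, with NDUFV3 and NDUFA3 1.45-fold and 1.39-fold lower and NDUFS4 1.25-fold higher. Mitochondrial ribosomal proteins had a median of -0.12 over 72 genes, with 15 random lists as low; 53 were below 0, MRPS18B being 1.54-fold lower. MRPL18 went the other way, 2.28-fold higher, and was the 1 member at 2-fold.

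Other mitochondrial groups lay within the random lists. Import subunits had a median of -0.05 over 20 genes, with TIMM8A 1.42-fold lower and TIMM17A 1.28-fold higher. Genes of mitochondrial dynamics and biogenesis had a median of -0.09 over 26 genes, in which the coactivator gene PPRC1 was 2.01-fold lower and its relative PPARGC1A 1.76-fold higher; PPRC1 was under 2-fold after lowess centring, with a log2 difference of -0.96. Enzymes of the tricarboxylic acid cycle had a median of -0.16 over 22 genes at the percentile 0.61, just inside the limit, with OGDH 1.61-fold and DLAT 1.47-fold lower and the kinase gene PDK4 1.75-fold higher. That list was below the limit under 4 alternatives, among them lowess centring (-0.15). Of 15 mitochondrially encoded genes asked for, 0 were on the array as named genes.

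**Figure D3:**
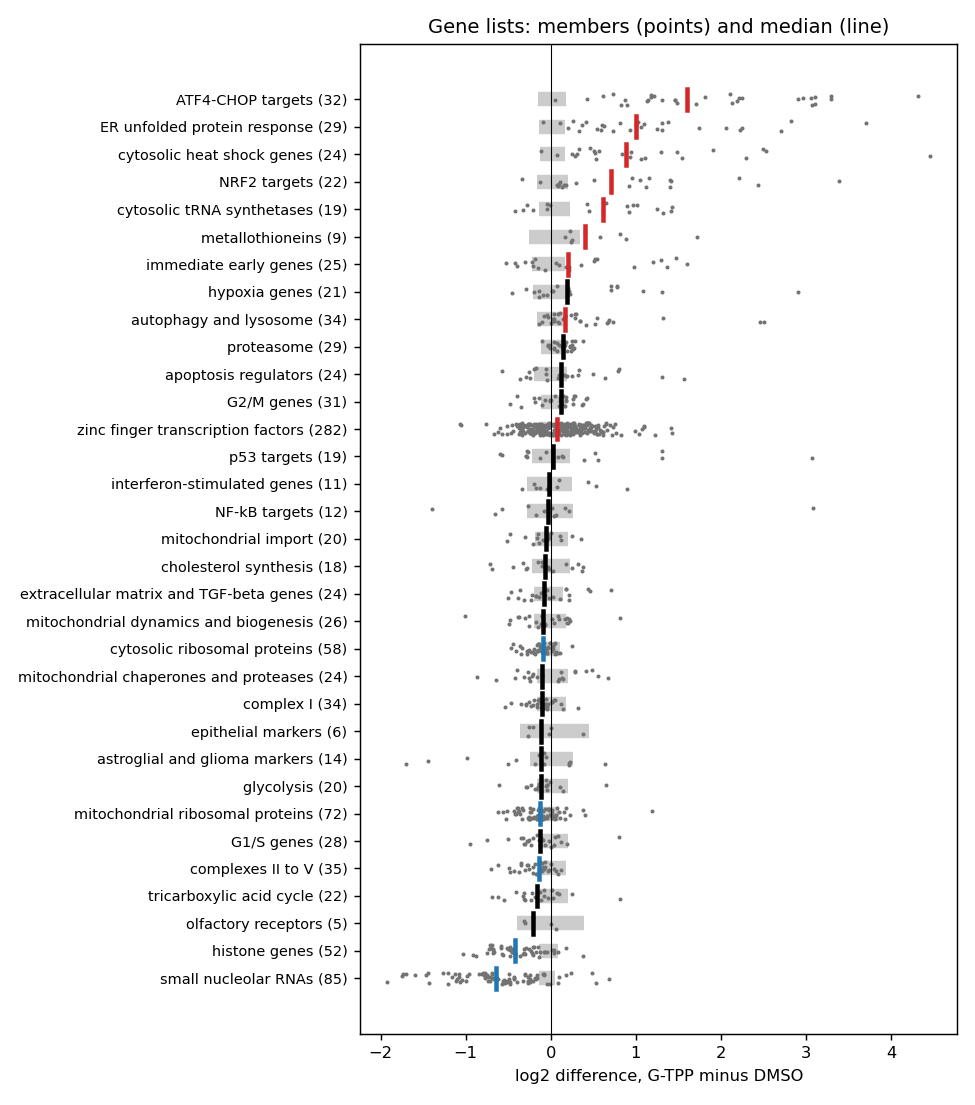
Log2 difference of each kept member (grey points) and its median (vertical line) for the 33 gene lists with at least 5 kept genes, number of kept genes in parentheses, with grey boxes for the range of the random lists, which leaves out 0.5% of them at either end. Medians in red lie above the random lists, in blue below and in black inside; the ATF4-CHOP list is at 1.60 and small nucleolar RNAs at -0.65.

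NRF2 target genes, which answer to oxidants and electrophiles, had a median log2 difference of 0.71 over 22 genes, above all 10000 random lists, and 9 were at least 2-fold higher. HMOX1 went from 380.4 to 3987, and the cystine transporter gene SLC7A11, which is also an ATF4 target, was 4.65-fold higher. The aldo-keto reductase AKR1B10 was at least 2.20-fold higher, and AKR1C1 was 2.65-fold higher by its brighter probe set but had a log2 difference of 0.35 by the other. Metallothionein genes and their partners had a median of 0.40 over 9 genes, all above 0, with 22 random lists as high; the zinc exporter gene SLC30A1 was 3.29-fold higher, MT1F 1.84-fold and the metal-sensing factor MTF1 1.76-fold. Autophagy and lysosome genes had a median of 0.17 over 34 genes, with 20 random lists as high and 28 above 0. In that list GABARAPL1 (5.70-fold), WIPI1 (5.52-fold) and MAP1LC3B (a log2 difference of 1.32), all of autophagosome formation, reached 2-fold, and ATG13 was 1.65-fold higher. Without the dimmer genes, at the 75th percentile filter, the median was 0.10 and the list lay inside. When the mean (0.38) replaced the median, the list lay above the random lists. Proteasome subunits had a median of 0.15 over 29 genes and lay inside at the percentile 98.7, with PSMA5 1.30-fold higher and none at 2-fold.

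Immediate early genes had a median of 0.20 over 25 genes, with 27 random lists as high. The phosphatase genes DUSP1 (3.02-fold) and DUSP6 (2.57-fold), JUN (2.77-fold) and NR4A2 were among the 5 that were at least 2-fold higher, though NR4A2 was dim with DMSO and under 2-fold when set against the floor. The list lay inside after quantile normalization (0.16) and at the 75th percentile filter (0.21). Apoptosis regulators had a median of 0.13 over 24 genes and lay inside at the percentile 97.46. Within them PMAIP1, which encodes the BH3-only protein NOXA, was 2.96-fold higher and the death receptor gene TNFRSF10B 2.48-fold higher, and the anti-apoptotic genes CFLAR and MCL1 were 1.74-fold and 1.73-fold higher. Target genes of p53 lay inside with a median of 0.03 over 19 genes, and also with a mean of 0.25 and, at the 75th percentile filter, a median of 0.33 over 10 genes, with GDF15, TNFRSF10B and PLK2 (2.47-fold) at 2-fold and POLH 1.51-fold lower. Hypoxia genes lay inside with a median of 0.19 over 21 genes, and above the limit when the mean (0.37) replaced the median; with no brightness filter the median was 0.07 over 23 genes. DDIT4, VEGFA (2.47-fold) and P4HA2 (2.11-fold) reached 2-fold in that list, of which 10 of the 24 genes asked for also belong to other lists.

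NF-kB targets pointed both ways. The list's median log2 difference was -0.03 over 12 genes, its mean was 0.04 and it lay inside the random lists. IL1A, the cytokine interleukin 1 alpha, went from 86.8, within the range of the floor, to 732.4 (at least 4.24-fold higher), and the chemokine gene CCL2 went from 1275 to 486.2 (2.62-fold lower). TNFAIP2 was 1.58-fold lower, BCL3 had a log2 difference of -0.57, and NFKBIA, the inhibitor of NF-kB, had a log2 difference of -0.27. Interferon-stimulated genes had a median of -0.02 and a mean of 0.10 over 11 genes and lay inside, with IRF1 1.86-fold higher and IRF7 1.26-fold lower.

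Cell cycle and metabolic lists lay inside the random lists. Genes of the G1/S transition had a median log2 difference of -0.13 over 28 genes at the percentile 0.81, with the cyclin genes CCNE1 and CCNE2 1.93-fold and 1.69-fold lower, PCNA 1.42-fold lower and CDC6 1.74-fold higher. That list was below the limit under lowess centring (-0.12) and with the mean (-0.16). Mitosis genes of G2/M had a median of 0.12 over 31 genes, with KIF2C 1.34-fold higher and BUB1B 1.40-fold lower. Cholesterol synthesis had a median of -0.07 over 18 genes, in which INSIG1 and LSS were 1.65-fold and 1.61-fold lower. Glycolysis had a median of -0.11 over 20 genes, with PFKM 1.52-fold lower, the glucose transporter SLC2A3 1.56-fold higher and HK2, the mitochondria-bound hexokinase, at -0.06. Extracellular matrix and TGF-beta genes had a median of -0.08 over 24 genes, with TIMP1 1.42-fold lower and LOX 1.63-fold higher. The control genes ACTB and GAPDH had log2 differences of -0.11 and -0.06.

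Small nucleolar RNAs, which guide modification of ribosomal RNA and are mostly cut from introns, formed the largest block of low values. Their median log2 difference was -0.65 over 85 genes, below all 10000 random lists; 78 were below 0, 19 were at least 2-fold lower and none at least 2-fold higher. With no brightness filter the median was -0.26 over 176 genes, again below all random lists. After SNORD30 came SNORD60 (3.36-fold lower), SNORD75 (3.34-fold) and SNORD78 (3.26-fold), and 8 of the 15 genes with the lowest differences were small nucleolar RNAs. MIR17HG, the host transcript of the miR-17-92 cluster, went from 270.4 to 85.4, within the range of the floor. Histone genes had a median of -0.42 over 52 genes, below all random lists, with 46 below 0; H3C8 was 2.05-fold, H1-3 1.89-fold and H2AC15 1.84-fold lower. H3C8 was under 2-fold when the median of all genes was set to 0. Cytosolic ribosomal proteins had a median of -0.09 over 58 genes, with 8 random lists as low and none of the genes at 2-fold. RPL23 was 1.39-fold and RPS27 1.36-fold lower, and the list lay inside with no brightness filter (-0.08) and with random lists matched in 5 bins (-0.09). Zinc finger genes of the ZNF family had a median of 0.07 over 282 genes, above all random lists, with 7 at least 2-fold higher, among them ZNF841 (2.69-fold), and 2 at least 2-fold lower. The median was 0.04 over 439 genes with no filter, 0.14 after lowess centring and 0.23 over 63 genes at the 75th percentile filter, and the list lay above the random lists each time.

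Markers of astroglial and glioma cells lay inside as a list, with a median of -0.11 over 14 genes, and below the limit when the mean (-0.31) replaced the median. SOX2, a transcription factor of neural stem cells, went from 4434 to 1629 (2.72-fold lower), PDGFRA was 3.25-fold lower and SOX9 1.98-fold lower, while the glutamate transporter gene SLC1A3 was 1.56-fold higher. Markers of cell types foreign to the culture were mostly under the filter. Kept were 2 immune genes with a median of -0.33 (TYROBP and CD68), 2 endothelial genes with -0.12 (CLDN5 and CDH5), 4 neuronal genes with -0.29 and 1 blood or liver gene (APOA1) with -0.04, too few for a comparison with random lists. With no brightness filter these lists lay inside. Their medians were then -0.12 over 13 immune, -0.07 over 12 endothelial, -0.16 over 13 neuronal and -0.16 over 7 blood or liver genes. Epithelial markers had a median of -0.11 over 6 genes and lay inside, as did the 5 olfactory receptors that passed the filter (-0.21).

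Genes outside the lists also lay at the ends. CMKLR2, a chemerin receptor, went from 98.8 to 1556 (at least 9.01-fold higher), and SLFN5, a Schlafen family gene, was 10.3-fold higher. At the low end the deubiquitinase gene USP2 was 2.84-fold lower, NREP 2.78-fold and the glucose transporter gene SLC2A12 2.63-fold. Folds written as "at least" set the brighter array against a floor, the intensity under which 95% of olfactory receptors lay (172.6 with DMSO), because the dimmer array was under it. With all intensities raised to the floor of their array, 287 genes were at least 2-fold higher and 58 at least 2-fold lower. Of the 33 lists set against random lists, 9 lay above, 5 below and 19 inside. The percentiles alone would put 0.33 of them outside by chance, which is a low estimate, since 1.7% of unchanged simulated lists of 25 genes lay outside and genes of a list vary together. The percentiles describe these 2 arrays and not the conditions, and a difference between cultures that has nothing to do with G-TPP would look the same.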

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

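Of the tests in this part, the comparison of RNAs by length, the brightest genes alone, the count without the stress lists and the chaperones without very bright probe sets were chosen only after the result was seen. With 1 array per group no sample can be an outlier and no effects of 2 groups can be compared. The bootstrap and binomial intervals in this part treat genes as independent, which they are not. They hold no difference between cultures, so they describe genes of these 2 arrays and not the conditions.

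Signal outside the gene comparison was seen in probe sets that carry no single gene name. Of 3987 unlisted probe sets above the filter 81 were at least 2-fold higher and 48 at least 2-fold lower in the G-TPP array, and of 1006 with several symbols 24 were higher and 19 lower.

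Small nucleolar RNAs were low together, at a median log2 difference of -0.73 for 51 C/D box genes (SNORD) and -0.53 for 34 H/ACA box genes (SNORA). A lower yield of all short RNAs by a like amount in the G-TPP sample is argued against by 21 other short RNAs, but only for their types. They were chosen by type and not by length, SCARNA genes are among them, and microRNA genes were left out by rule. Their median was -0.09 (95% bootstrap interval -0.18 to 0.23), with 13 of the 21 below 0. Loss by length alone is argued against only for RNAs of 100 to 200 bases, where 38 small nucleolar RNAs lay -0.55 (-1.11 to -0.27) from 12 others. The rest of the 85 were not compared by length. The median of 30 microRNA genes was -0.30 (-0.41 to -0.21), with 27 below 0, which goes with a wider loss. Loss of RNAs outside that length range therefore stays open. Lower host transcripts stay open. A kept host was found for 42 of the 85, in 32 hosts, and SNORD30, SNORD60, SNORD75 and SNORD78 were not among them. Over these hosts the host exceeded its small nucleolar RNAs by a median of 0.45 (0.28 to 0.58), more than the 0.2 that this explanation allows. But the lower end is under the 0.3 fixed in advance, and stable host mRNA could lag behind its introns. A drop in ribosome production with G-TPP may also be involved, which the 2 arrays leave as a hypothesis.

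More genes were higher than lower, 310 against 61. A brightness-dependent trend between the arrays is argued against by lowess centring, after which 88.4% of the genes past 2-fold were higher. A floor that hides low genes is argued against by the 2218 brightest genes, with 87.5% of those past 2-fold higher (63 of 72; exact Clopper-Pearson 95% interval 77.6% to 94.1%). Members of the lists above the random ones hold 79 of the 310, and without them the share was 79.7% (74.6% to 84.1%). The listed genes alone thus do not make the excess. This is a count and no independent test, as those lists were called on the same data. Stress genes that no list holds may remain among the others. Whether the excess comes from G-TPP or from a difference between the cultures was not tested, as each condition has 1 array.

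Mitochondrial chaperones and proteases stayed inside the random lists, while the lists of cytosolic heat shock genes and of the ER unfolded protein response lay above them. The 17 members outside the brightest 10% of genes had a median log2 difference of -0.21. That was at the percentile 0.775, close to the lower limit and far from the upper one. Very bright probe sets that cannot rise further therefore do not account for these 17, and whether they held down the brightest members was not tested. This is no independent test. The upper quartile of all 24 members was 0.18, so a high median without the brightest was hardly possible. Single members lay on both sides, 11 above 0 and 13 below. GRPEL2 was 1.59-fold, LONP1 1.47-fold, HSPE1 1.40-fold and HSPA9 1.33-fold higher, and PMPCA was 1.83-fold and HTRA2 1.57-fold lower. As a list these transcripts may respond later than 6 h or not at all, and no other time was measured.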

How the results depend on the processing

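All settings in this part were fixed before the data were examined, except the floor, which was chosen after they were seen. No paired analysis was possible because there was 1 array per group, and for the same reason no replicate could be left out. The count of higher genes stayed between 233 and 334 at 2-fold over the alternatives of filter, scaling, probe set and pseudocount. With intensities raised to the floor they were 287 higher and 58 lower. At 1.5-fold the counts were 816 higher and 357 lower, and at 3-fold 97 and 7. At the 75th percentile filter 37 were lower, since fewer genes were counted. The share of higher among genes past 2-fold was 82.0% to 88.4% over the scalings.

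No list that lay outside the random lists changed direction. The tricarboxylic acid cycle came to lie below the random lists under lowess centring (-0.15), quantile normalization (-0.19), the 75th percentile filter (-0.21) and the mean (-0.15). The G1/S genes did so under lowess centring (-0.12) and the mean (-0.16), astroglial and glioma markers under the mean (-0.31), and hypoxia genes lay above under the mean (0.37). Immediate early genes lost their place after quantile normalization (0.16) and at the 75th percentile filter (0.21), where autophagy and lysosome genes (0.10) did too. Complexes II to V did so with no filter, the 75th percentile filter and without shared genes (-0.12 each), and cytosolic ribosomal proteins with no filter (-0.083) and 5 bins (-0.090). The cause was not tested. The small medians of NF-kB, interferon, p53 and epithelial genes, and the value of APOA1, changed sign under some settings.

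Of the 67 named genes past 2-fold, 65 to 67 were still past it under each of the 5 alternatives run for them, those of scaling, pseudocount and probe set mean. Most of these were named for their large differences, so this was likely in advance. Of all 371 genes past 2-fold, 340 to 367 were still past it under the same alternatives. ATF4 (0.40) and AKR1C1 (0.88) dropped under it with the mean of their probe sets. Signal over background limits dim genes, whose changes near the floor read as small folds.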

Other observations

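The lists in this part were written after the data had been looked at, except that of ribosome biogenesis factors, whose test was fixed before its members were seen, and genes named here were chosen after their values were seen. Placing such a list among random lists describes it and is no independent test. The neural progenitor list without some of its members was also run only after its result was seen.

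Genes of transport between the ER and the Golgi, none of them in the fixed lists, lay mostly above 0 in the G-TPP array. Over 57 genes of translocation, COPII and COPI coats, tethers and fusion the median log2 difference was 0.32, above all 10000 random lists of like brightness, and 49 were above 0. STX5, the Golgi syntaxin, had a log2 difference of 1.58 and the COPI regulator ARFGAP3 one of 1.32, the giant tether gene GOLGB1 was 2.88-fold higher and the export receptor gene MIA2 2.52-fold. Both coats were represented, with SEC23B of COPII 1.59-fold and COPG1 of COPI 1.68-fold higher, while KDELR1 was 1.14-fold lower. Of 15 amino acid transporter genes, 4 were at least 2-fold higher, SLC1A4 at 4.39-fold, SLC38A2 at 2.71-fold, SLC43A1 at 2.35-fold and SLC7A1 at 2.15-fold. But the list's median of 0.11 lay inside the random lists, and SLC7A6 was 1.59-fold lower. Transporter genes of the ATF4-CHOP list, such as SLC7A11 (4.65-fold higher) and SLC7A5, are not in it. All kept members of that list were above 0, so the median of 0.11 does not describe amino acid transporters as a whole.

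A list of neural progenitor transcription factors was written after SOX2 and other low genes had been seen. Over its 24 kept genes the median log2 difference was -0.29, and 1 of the 10000 random lists was as low; 20 were below 0. SOX2 (2.72-fold), SALL1 (2.11-fold), the chromatin remodeller gene CHD7 (2.10-fold) and POU3F2 (2.01-fold) were at least 2-fold lower, SOX21 was 1.95-fold and HES1 1.88-fold lower, and ZEB1 was 1.33-fold higher. Without genes of the fixed lists the median was -0.29 over 22 genes, with 2 random lists as low. Leaving out SALL1, CHD7 and POU3F2 as well, it was -0.21 over 19 genes, inside the random lists, but these were taken out for their low values, which moves the median up by construction, so this decides nothing. The placement describes a list prompted by the same data.

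The list of RNA polymerase subunits had a median of -0.29 over 28 genes, below all 10000 random lists, with 21 below 0 and 7 above. POLR2A, the catalytic subunit of RNA polymerase II, went from 1264 to 631.6. The polymerase III genes POLR3C and POLR3F were 1.34-fold and 1.28-fold higher, while POLR3K was 1.57-fold lower. One hypothesis is that genes of ribosome production as a group may be lower with G-TPP. It was tested on 53 ribosome biogenesis factors outside the polymerase and UTP families, where the median was -0.29, below all random lists, with 43 of 53 below 0. MYBBP1A was 1.70-fold, RRS1 1.65-fold and NOP16 1.61-fold lower, none reached 2-fold, and NPM1 was 1.06-fold lower. The values are those the hypothesis needs, but it was found and tested on the same 2 arrays, and an unrelated difference in growth between the cultures could give the same picture.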
